A study of Mus musculus with 12 samples.

How the data were processed

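Liver RNA of mice aged 12 months was measured in 12 libraries, 3 in each of 4 groups given by the genotype and sex in the labels: wild-type males, OXR1A-deficient (knockout) males, wild-type females and knockout females. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, poly(A) RNA was captured with oligo(dT) beads and copied with random primers, and the amplified cDNA was made into single-stranded circles. The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), per the file headers, for 18560 genes, rounded to 2 decimals. Reads were aligned with TopHat2 to mouse build mm10, per the submitters' processing notes; the roles of the 2 names are read from what they usually are, and the quantifier, the annotation release, the filters and the read totals are not given in the sources used here. No column of per-sample values was left out (0 columns). The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

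Depth was not stated. In genes of low value the FPKM of a gene are whole multiples of what 1 read is worth, and 866 values of 200 genes gave each library's relative depth, from 0.93 to 1.41 with wild-type female 1 at 1.0. The recovered values lay 0.122 of a read from a whole number on average, against 0.216 at the lowest for random step sizes and 0.25 for values with no steps. The recovered steps were fitted to make this distance small and the random ones were not. The gap between them therefore does not by itself show that the depths are right. The steps give relative depth only, so no counting intervals were made. In any pair of libraries at most 0.33% of the values of genes with at least 5 FPKM were identical, and all 12 libraries were kept as separate samples. A gene at 0 is described as listed at 0.

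Genes with at least 1 FPKM in at least 3 libraries (11514) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3: 1 mean per group over all 12 libraries, a contrast per comparison, and moderated variances with a trend on the mean (two-sided, Benjamini-Hochberg adjustment over all tested genes, called at an adjusted p under 0.05). Log2 changes are on this scale with their standard error (SE), which understates the change of low genes; folds are ratios of mean FPKM, and means are given ± SD over the 3 libraries of a group. The comparisons were knockout against wild type in males and in females, the difference between these effects (interaction), and males against females in wild type and in knockout. A count of genes whose 3 values in each group do not overlap comes to 10% by chance.

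Gene lists were fixed before the data were examined, 31 in all: genes biased to male and to female liver; growth hormone, STAT5 and the IGF system; lipogenesis; cholesterol synthesis; fatty acid oxidation; lipid uptake and storage; bile acids; glucose metabolism; oxidative stress; TLDc proteins and arginine methyltransferases; nuclear and hormone receptors; xenobiotic metabolism; circadian clock; interferon; acute phase; unfolded protein response; proliferation; fetal and tumour genes; periportal and pericentral hepatocyte genes; markers of stellate cells, macrophages, lymphocytes, sinusoidal endothelium, cholangiocytes, neutrophils, red cells, fat cells and exocrine pancreas; and Xist with Y-linked genes as a sex check. The 26 lists with at least 5 tested genes were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list moves one way on its own, were alternatives. Some genes stand in more than 1 list, and many markers of other cell types are not unique to them.

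Named genes followed a rule written before the data were examined: Oxr1 and the sex check genes; for each comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes without overlap (where none passed, the 3 with the smallest p, as values); and for each list and comparison up to 4 members with the smallest p. Other genes are named only where the text says that they were chosen after their values were seen. Members of near-identical families (Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Sult2a, Orm and Serpina1 genes) share sequence, so their separate values are uncertain where reads could be split between copies. Entrez gene numbers of 18502 genes matched the RefSeq gene table of GRCm38, from which coordinates were taken. Transcript lengths came from GENCODE mouse release 21 for 18140 genes (97.7%).

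Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a fit of only the 2 groups compared, no variance trend, array weights, the replicate number as a block, the 2 other list tests, and leaving out each library in turn. Alternatives chosen after seeing the data were removal of each library's smooth trend with transcript length (natural spline with 4 degrees of freedom, splines 4.3.3), the same with the replicate number as a block, leaving out the 3 libraries poor in long transcripts (wild-type male 2, knockout male 3, knockout female 2), and leaving out the 3 libraries with traces of transcripts of the other sex (knockout male 3, wild-type female 1, knockout female 1).

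The steps were tested on simulated data. For knockout against wild type in males, with 50 of the 11514 genes changed by each size, 96% were called at a log2 change of -2, 84% at -1, 78% at 1 and 96% at 2. Of 11290 unchanged genes 8 were called, and 0 of 25 other lists. The simulated genes varied independently, with the same spread in every group, and these changed genes had a mean log2 value above 2. In the real lists the estimated correlation between genes ran from 0.023 to 0.816. The simulation therefore does not show how often lists are called falsely in these libraries, or how often low genes are missed. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Sequencing reads, single isoforms and exons were not analysed here.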

Results

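Livers of mice aged 12 months were profiled by RNA sequencing in 12 libraries, 3 each from wild-type males, knockout males, wild-type females and knockout females. The knockout mice lacked OXR1A, a protein isoform made from Oxr1, a gene of the TLDc domain family known for its part in resistance to oxidative stress. The study asked how liver transcription differs without OXR1A, and its title points to fatty liver, hormone response and lipid metabolism in males. FPKM sums ran from 526203 in knockout male 1 to 667434 in wild-type male 2, and relative depth from 0.93 in knockout female 2 to 1.41 in wild-type male 2. Major urinary protein (Mup) transcripts made up 8.51% to 14.3% of the FPKM in wild-type males, 1.32% to 7.75% in knockout males, 2.19% to 3.70% in wild-type females and 1.14% to 1.71% in knockout females. Long transcripts were scarcer than on average in wild-type male 2, where the log2 deviation of a gene from its mean had a slope of -0.215 on log2 length, against -0.092 to 0.123 in the other libraries. The first principal component, with 46.1% of the variance, placed the wild-type males at -46.8 to -31.6, the knockout males at -23.1 to -5 and the females at 15.8 to 31.9.

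Oxr1 (Entrez gene 170719, GRCm38 chromosome 15, 41447482 to 41861051) was listed at 17.9 ± 5.61 FPKM in the wild-type males, with 12.1 in wild-type male 2, and at 23.4 ± 1.48 in the knockout males. It stood at 18.5 ± 1.85 in the wild-type females and at 20.2 ± 0.642 in the knockout females. Neither difference passed the limma test (log2 change 0.41, SE 0.18, adjusted p = 0.204 in males, 0.13, SE 0.18, adjusted p = 0.938 in females). The value covers all isoforms of the gene, so it does not check the loss of OXR1A in the libraries labelled knockout.

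Xist, the transcript of the inactive X chromosome, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d fitted the labelled sex in all 12 libraries. Xist was listed at 19.2 to 45.9 FPKM in females and at 0.04 to 0.08 in males other than knockout male 3, which had 0.82. Eif2s3y lay at 23.1 to 35.7 in males and at 0 to 0.10 in females other than wild-type female 1 with 1.89 and knockout female 1 with 0.85. Ddx3y was 0.57 in both of these female libraries and 0 to 0.02 in the other females. Between knockout and wild type, the 5 sex check genes gave no call in males (camera adjusted p = 0.964) or females (0.384).

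Knockout male livers held less RNA of some genes that mouse liver makes mainly in males, and more RNA of some genes that it makes mainly in females. Cyp2b9, a cytochrome P450 typical of female liver, rose from 0.727 ± 0.291 FPKM in wild-type males to 92.3 ± 48.4 in knockout males (log2 change 5.59, SE 0.36, adjusted p = 2.73e-05), against 431 ± 25.6 in wild-type females. Hsd3b5, a steroid dehydrogenase typical of male liver, fell from 74.4 ± 5.82 to 3.13 ± 4.24 (log2 change -4.72, SE 0.53, adjusted p = 0.00196). Selenbp2, a selenium-binding protein, fell from 171 ± 51.4 to 17.4 ± 0.385 (log2 change -3.18, SE 0.21, adjusted p = 2.73e-05). Lcn2, the acute phase protein lipocalin 2, rose 12.0-fold, and Cidea, a lipid droplet protein, rose 16.3-fold from 1.35 ± 1.04 to 22.0 ± 6.98 FPKM.

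Knockout against wild type in males gave 294 called genes of 11514 tested, 245 up and 49 down, of which 73 and 28 differed by more than 1 on the log2 scale. At an unadjusted p under 0.05 there were 2752 genes, and in 23.7% of the tested genes the groups did not overlap (10% by chance). The median log2 difference of all genes was 0.19, and median-ratio scaling took it to 0.02, so log2 changes given for males are higher by 0.19 than those relative to the median gene. With median-ratio scaling 152 genes were called, 72 up and 80 down; with quantile normalization 140, 61 up and 79 down; with the length trend removed, chosen after seeing the data, 353, 150 up and 203 down. The count of called genes also rested on single libraries. It was 145, 122 and 58 without wild-type male 1, 2 and 3, and 112, 81 and 570 without knockout male 1, 2 and 3. Leaving out a female library, which serves only the estimate of the spread, gave 152 without wild-type female 1 or 2, 207 without wild-type female 3, and 160, 155 and 157 without knockout female 1, 2 and 3. A fit of the 6 male libraries alone called 3 genes. The 294 and the adjusted p-values in males thus rest on the estimate of the spread shared with the female libraries. Array weights gave 44 up and 19 down, and the replicate number as a block 103 and 29. Of the 50 called genes named for males, 16 were called whichever library was left out: Cyp2b9, Selenbp2, Hsd3b5, Lcn2, Cidea, Slc22a27, Orm2, Orm3, Cd36, Nsdhl, Idi1, Cyp2c38, Cyp2c39, Dnajb9, Gpr182 and Cdh1. Among the others, Abcd2 and Igfbp2 were called in only 1 of the 12 such fits, Rhbg in 2, and Cyp2b13, Dcn and Mt1 in 3. All 294 genes kept the direction of their change in every fit that left out a library. Leaving out a female library cannot alter a change in males, and choosing genes by p in these libraries favours a kept direction.

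**Figure D1:**
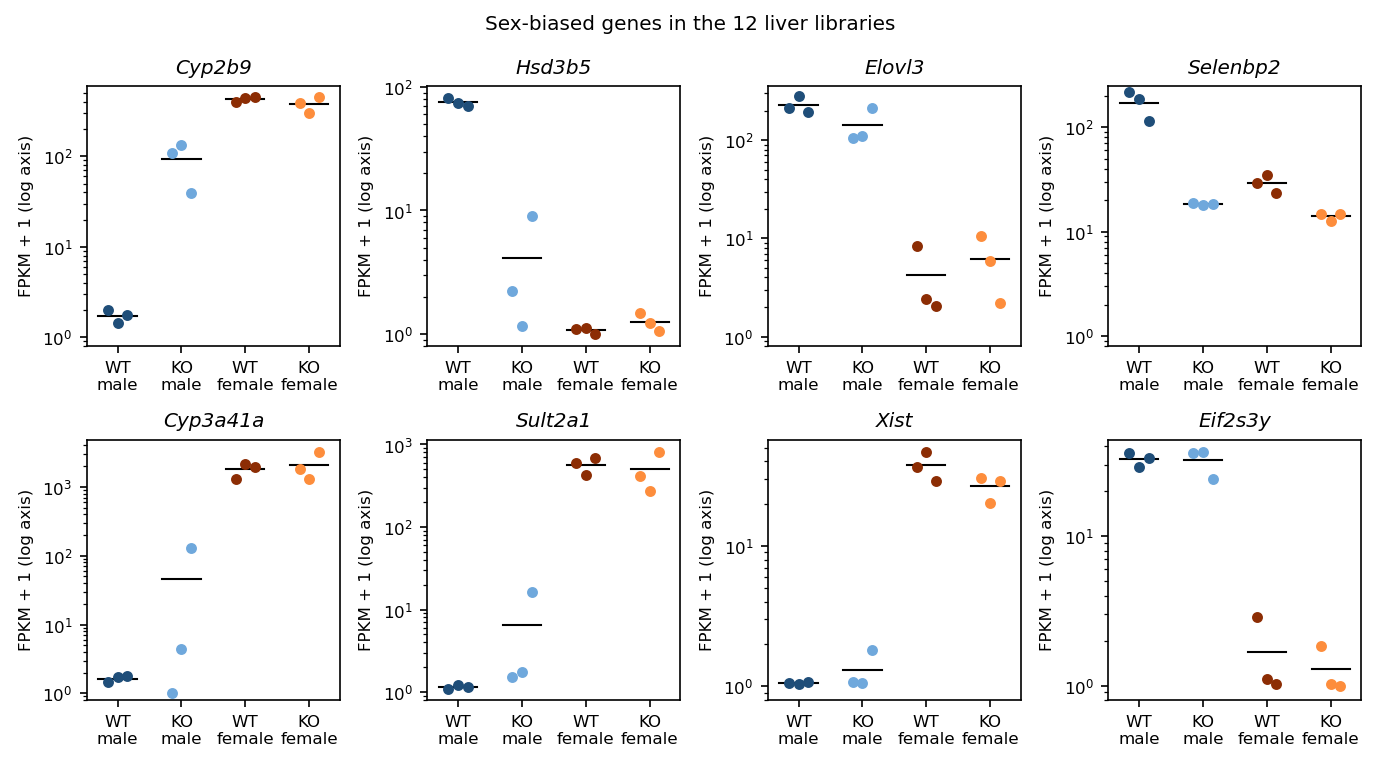
Levels of 8 sex-biased genes in each library (points) and their group means (lines), as FPKM + 1 on a log axis, for wild-type (WT) and OXR1A-deficient (KO) males and females. Cyp2b9 lies at 38.1 to 131 FPKM in the 3 knockout males and at 0.42 to 1 in the wild-type males, while Xist lies at or below 0.82 in every male library.

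Among the 25 tested genes of the male-biased list, 7 fell in knockout males and 18 did not pass the test; adjusted over the list alone, 18 fell. Besides Hsd3b5 and Selenbp2, Serpina1e fell 8.18-fold to 796 ± 606 FPKM, the pheromone carrier Mup20 fell 4.46-fold to 2617 ± 1437, Cyp4a12b fell 4.26-fold and the complement gene C6 fell 2.50-fold. The organic anion transporter Slco1a1 stood at 13.2 ± 12.1 against 68.8 ± 18.8 without passing (adjusted p = 0.0539). The list's median log2 change was -1.04 (camera adjusted p = 2.98e-35, and adjusted p = 0.0437 with an estimated correlation). Outside the list, Mup21 fell 3.81-fold, Cib3 17.7-fold and Igfbp2, an IGF-binding protein, 3.44-fold. The Mup share was lowest in knockout male 2 (1.32%) and highest in knockout male 3 (7.75%), the library with an Xist trace.

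In the female-biased list, 4 of 34 genes rose in knockout males and 30 did not pass; adjusted over the list alone, 11 rose. Beside Cyp2b9 these were Cyp2b13 (0.0567 ± 0.0493 to 5.38 ± 3.93 FPKM), the anion transporter Slc22a27 (1.49 ± 0.455 to 11.1 ± 4.59) and the peroxisomal transporter Abcd2 (3.75 ± 1.27 to 8.62 ± 1.44). The prolactin receptor Prlr was at 50.9 ± 12.5 against 23.5 ± 9.54 (adjusted p = 0.0599). The median log2 change was 1.03 (camera adjusted p = 0.000125, but adjusted p = 0.327 with an estimated correlation, and 0.0625 without the 3 libraries poor in long transcripts). Cyp3a41a and Sult2a1 were chosen for this comparison after their values were seen. In knockout males 1, 2 and 3, Cyp3a41a was listed at 0, 3.39 and 129 FPKM, Sult2a1 at 0.52, 0.77 and 15.5 and Xist at 0.08, 0.05 and 0.82, so the levels of Cyp3a41a and Sult2a1 in knockout males came mainly from knockout male 3. Cyp2b9 was lowest in that library, at 38.1 FPKM against 108 and 131.

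Some genes of the acute phase list rose in knockout males. Lcn2 rose from 20.9 ± 14.0 to 251 ± 68.8 FPKM (log2 change 3.81, SE 0.54, adjusted p = 0.00917). The metallothioneins Mt1 and Mt2 rose 6.82-fold and 11.6-fold, the orosomucoids Orm2 and Orm3 rose 3.74-fold and 4.20-fold, and the pentraxin Apcs rose 2.44-fold. Of the 21 genes of the acute phase list, 8 rose and 13 did not pass; adjusted over the list alone, 12 rose. The median log2 change was 0.72 (camera adjusted p = 1.85e-05, and adjusted p = 0.216 with an estimated correlation).

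Some genes of lipid storage and sterol synthesis rose in knockout males, and most members of these lists did not pass. The fatty acid transporter Cd36 went from 18.8 ± 4.02 to 72.2 ± 17.9 FPKM (log2 change 1.87, SE 0.20, adjusted p = 0.00172), the droplet protein Cidec rose 3.80-fold and the lipase Mgll 1.69-fold. Apoa4, an apolipoprotein secreted with lipid, rose 5.32-fold. Among 30 genes of lipid uptake and storage, 5 rose, among them Cd36, Cidea, Cidec and Mgll, and 25 did not pass (12 up and 1 down adjusted over the list alone, median 0.40, camera adjusted p = 0.0284, and adjusted p = 0.29 with an estimated correlation). That list call was lost without wild-type male 1 (0.157), wild-type male 3 (0.108) or knockout male 3 (0.11). In cholesterol synthesis, Idi1 rose 2.94-fold, Hmgcs1 2.51-fold, Nsdhl 2.22-fold and Cyp51 2.16-fold. In all, 6 of 24 genes rose and 18 did not pass (10 up adjusted over the list alone, median 0.55, camera adjusted p = 0.00321, and adjusted p = 0.474 with an estimated correlation), and the call was lost without the 3 libraries poor in long transcripts (0.0567). Among 29 genes of fatty acid oxidation, 8 rose and 21 did not pass (13 up adjusted over the list alone, median 0.41, camera adjusted p = 0.00207, and adjusted p = 0.448 with an estimated correlation). Vnn1 rose 2.95-fold, Cyp4a14 3.05-fold and the hormone Fgf21 6.40-fold, and the electron transfer enzyme Etfdh rose from 110 to 165 FPKM. The call of this list was lost without knockout male 3 (0.108), and both it and the lipid uptake call without the 3 libraries with traces of the other sex (0.0653 each). Both of these sets of 3 libraries were chosen after the data were seen. The lipid uptake call was also lost with a pseudocount of 0.1 (0.0523) and among genes with a mean FPKM of at least 5 (0.091). Of the 20 lipogenesis genes 0 were called, also when adjusted over the list alone. Elovl5 stood at 244 ± 49.8 against 180 ± 41.5 (adjusted p = 0.238) and Thrsp at 200 ± 208 against 388 ± 132 (adjusted p = 0.265). The list had a median of 0.09, a mean of -0.01 and a camera call downwards against other genes (adjusted p = 0.0157, and adjusted p = 0.515 with an estimated correlation). The call was lost without wild-type male 3 (0.172), knockout male 1 (0.0635) or knockout male 3 (0.29) and with either scaling (0.089 and 0.738).

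Some markers of liver macrophages and sinusoidal endothelium rose in knockout males. The Kupffer cell genes Cd5l, Vsig4, Emr1 and Timd4 rose 2.94-fold, 2.02-fold, 3.68-fold and 3.47-fold. Of the 15 macrophage genes 6 rose and 9 did not pass (14 up adjusted over the list alone, median 1.02, camera adjusted p = 1.12e-06, and adjusted p = 0.327 with an estimated correlation). The mean score of the macrophage list was 5.125 in knockout male 2 against 3.994 and 4.295 in the other knockout males and 2.987 to 3.666 in the wild-type males. Knockout male 2 was also highest of the male libraries in stellate (3.094) and lymphocyte (2.247) scores. The endothelial genes Gpr182, Cdh5, Oit3 and Lyve1 rose 1.94-fold, 2.11-fold, 1.53-fold and 4.01-fold. Of the 15 endothelial genes 6 rose and 9 did not pass (12 up adjusted over the list alone, median 0.56, camera adjusted p = 1.12e-06, and adjusted p = 0.216 with an estimated correlation).

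Other cell types were tested in knockout males as well. Of 12 stellate cell and matrix genes, Dcn, the proteoglycan decorin, rose 1.68-fold and 11 did not pass (2 up adjusted over the list alone, median 0.53, camera adjusted p = 0.034, and adjusted p = 0.474 with an estimated correlation). The call was lost without wild-type male 1 (0.239), knockout male 1 (0.0641) or knockout male 2 (0.178). The lymphocyte list had 0 called genes of 11, also when adjusted over the list alone, a median of -0.02, a mean of 0.04 and a camera call downwards (adjusted p = 0.0415, and adjusted p = 0.515 with an estimated correlation). It was lost without wild-type male 2 (0.604), knockout male 1 (0.141) or knockout male 3 (0.642) and with either scaling (0.499 and 0.46). The 5 cholangiocyte genes were not called (median 0.04, camera adjusted p = 0.159). Too few genes were tested for camera in neutrophils (4 genes, median 0.52, 2 up adjusted over the list alone), red cells (4, median -0.31), fat cells (1, log2 change 0.15), exocrine pancreas (1, log2 change -0.41, down when adjusted over the list alone) and fetal and tumour genes (2, median 0.19). None of these genes was called over all genes tested.

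Genes of interferon response were higher in all 24 members in knockout males, with a median of 1.04, but 0 were called by limma over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.474 with an estimated correlation, fry adjusted p = 0.105). Ifit1 was at 6.82 ± 5.48 against 1.64 ± 0.211 FPKM (adjusted p = 0.0851) and Rsad2 at 4.88 ± 3.75 against 1.19 ± 0.341 (adjusted p = 0.0827). Knockout male 2 was highest, at 13.1 and 9.21. In the unfolded protein response, the chaperone Dnajb9 rose 3.14-fold and 17 of 18 genes did not pass (11 up adjusted over the list alone, median 0.61, camera adjusted p = 0.00201, and adjusted p = 0.343 with an estimated correlation). Herpud1 stood at 208 ± 49.2 against 117 ± 20.4 (adjusted p = 0.0618). None of 31 oxidative stress genes was called over all genes, while 11 were up and 2 down adjusted over the list alone (camera adjusted p = 0.0871). Hmox1 stood at 22.6 ± 9.42 against 10.1 ± 0.327 (adjusted p = 0.065) and Srxn1 at 23.8 ± 13.6 against 10.5 ± 1.01 (adjusted p = 0.0737), both highest in knockout male 2. The lists of TLDc proteins and arginine methyltransferases (camera adjusted p = 0.0871, 2 up adjusted over the list alone), proliferation (0.0871, 3 up) and nuclear and hormone receptors (0.964, 1 up) had 0 genes called over all genes and no call by camera. By fry, which tests a list on its own, the list of TLDc proteins and arginine methyltransferases was called upwards (adjusted p = 0.00181, 10 of 11 differences positive, median 0.30 beside the median of 0.19 over all genes), and so were the oxidative stress genes (0.0439).

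Of 11 periportal hepatocyte genes 1 fell in knockout males. Cdh1, which encodes E-cadherin, fell 5.66-fold from 7.96 ± 2.53 to 1.41 ± 0.461 FPKM, and the other 10 genes did not pass (4 down adjusted over the list alone, median -0.32, camera adjusted p = 9.25e-07, and adjusted p = 0.0865 with an estimated correlation). Among them were Gls2 at 81.0 ± 22.3 against 127 ± 16.1 (adjusted p = 0.0728) and the urea cycle gene Ass1 at 1241 ± 376 against 2036 ± 382 (adjusted p = 0.0939). Of 12 pericentral genes, the ammonium transporter Rhbg rose 3.26-fold and Cyp27a1, a sterol hydroxylase of bile acid synthesis, fell 1.46-fold (2 up and 2 down adjusted over the list alone, median 0.24, mean 0.21, camera downwards, adjusted p = 0.203). Among 19 xenobiotic genes, Cyp2c38, Cyp2c39 and the retinal dehydrogenase Aldh1a1 rose 2.38-fold, 3.92-fold and 2.01-fold and the carboxylesterase Ces2a fell 1.95-fold (3 up and 2 down adjusted over the list alone, median -0.04, mean 0.13, camera downwards, adjusted p = 0.12).

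In 4 more lists of knockout males, camera called a fall against other genes while the median lay near 0, below the shift of 0.19 in all genes. Of 21 bile acid genes 1 fell, Cyp27a1, and 3 adjusted over the list alone (median 0.01, mean -0.08, camera adjusted p = 0.00325). The 18 clock genes had a median of 0.04 and a mean of -0.02 (camera adjusted p = 0.00347). Of 18 growth hormone and IGF genes 1 fell, Igfbp2, with 2 up and 1 down adjusted over the list alone (median 0.00, mean -0.09, camera adjusted p = 0.0284; fry gave 0.915, upwards). Of 16 glucose genes 0 were called, also adjusted over the list alone (median -0.01, camera adjusted p = 0.00321). With an estimated correlation these 4 lists had adjusted p = 0.327, 0.327, 0.327 and 0.29. The bile acid call was lost without knockout male 2 (0.0748), and the growth hormone call without wild-type male 1 (0.203), wild-type male 2 (0.0535) or knockout male 2 (0.351). With quantile normalization all 4 calls were lost (0.247, 0.264, 0.662 and 0.12).

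**Figure D2:**
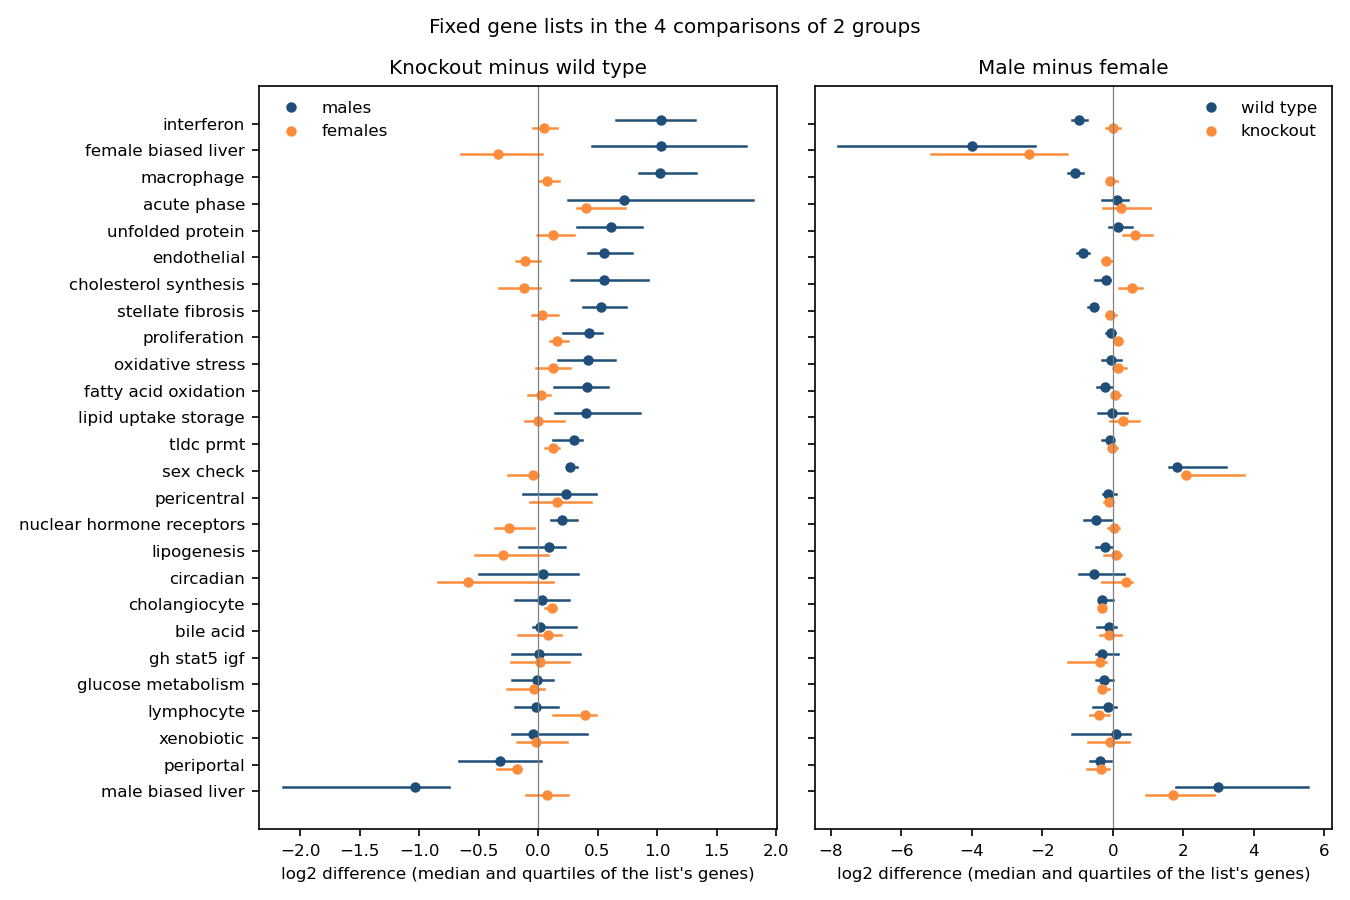
Median (point) and quartiles (line) of the log2 differences of the tested genes of each of the 26 fixed lists, knockout minus wild type in males and females on the left and males minus females in wild type and knockout on the right; gh stat5 igf is the growth hormone and IGF list and tldc prmt the list of TLDc proteins and arginine methyltransferases. In males the male-biased list has a median of -1.04 and the female-biased, macrophage and interferon lists lie at 1.02 to 1.04, against a median of 0.19 over all genes.

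In females, knockout against wild type gave 2 called genes. The orosomucoid Orm2 rose from 21.5 ± 5.24 to 80.8 ± 13.8 FPKM (log2 change 1.87, SE 0.22, adjusted p = 0.0122), and 1810053B23Rik, a transcript of unnamed function, fell from 3.47 ± 0.220 to 0.543 ± 0.116 (log2 change -1.54, SE 0.17, adjusted p = 0.0122). At an unadjusted p under 0.05 limma gave 706 genes, the median log2 difference of all genes was 0.00, and 17.6% of the genes had groups without overlap (10% by chance). The count was 12 without wild-type female 3, 1 without wild-type female 1, and 0 without wild-type female 2 or any 1 of the 3 knockout females. It was 6 in a fit of the 6 female libraries alone and 229 with array weights. Leaving out wild-type female 1 and knockout female 1, the libraries with Y-linked traces, together with knockout male 3 gave 0, an alternative chosen after seeing the data.

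In knockout females 20 of the 21 acute phase genes had a positive difference, and the list's median of 0.40 was called by camera (adjusted p = 5.06e-10), but not with an estimated correlation (adjusted p = 0.135) or by fry (0.0861). Over all genes 1 member, Orm2, rose, and 3 when adjusted over the list alone. Orm3 was at 19.8 ± 0.987 against 9.10 ± 2.09 FPKM (adjusted p = 0.227), Orm1 at 985 ± 56.5 against 647 ± 81.3 (adjusted p = 0.587) and the haemoglobin carrier Hp at 1735 ± 80.3 against 1158 ± 129 (adjusted p = 0.714).

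Camera also called 4 more lists in females besides the clock genes. The female-biased list was called downwards (median -0.33, adjusted p = 0.00127, and adjusted p = 0.665 with an estimated correlation, 0 called of 34 and 1 down adjusted over the list alone), with Cyp2a4 at 125 ± 101 against 719 ± 291 (adjusted p = 0.39). Nuclear and hormone receptors were called downwards (median -0.25, adjusted p = 0.00718, and adjusted p = 0.744 with an estimated correlation, 0 called and 1 down adjusted over the list alone), and lost the call without wild-type female 2 (0.0559). The leptin receptor Lepr stood at 0.917 ± 0.307 against 3.10 ± 0.676 (adjusted p = 0.135). The periportal list was called downwards (median -0.18, adjusted p = 0.02, and adjusted p = 0.517 with an estimated correlation, 1 down adjusted over the list alone), with Cdh1 at 1.54 ± 0.405 against 3.68 ± 0.637 (adjusted p = 0.498). This call was lost without wild-type female 1 (0.0622), knockout female 1 (0.0512) or knockout female 3 (0.0842). The pericentral list was called upwards (median 0.16, adjusted p = 0.0281, and adjusted p = 0.517 with an estimated correlation, 0 called also when adjusted over the list alone). It was lost without wild-type female 1 (0.0531), wild-type female 3 (0.0967) or knockout female 1 (0.114).

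Clock genes varied within the wild-type females as well as between groups. Dbp, a transcription factor driven by the clock, was listed at 71.6, 90.8 and 4.44 FPKM in the wild-type females and at 9.92, 9.01 and 1.74 in the knockout females (adjusted p = 0.78). Per3 stood at 9.64 ± 7.92 in wild type against 0.923 FPKM in knockouts (adjusted p = 0.683) and Usp2 at 4.59 ± 3.70 against 0.487 ± 0.0764 (adjusted p = 0.587). Camera called the circadian list downwards (13 of 18 differences negative, median -0.59, adjusted p = 0.00496, and adjusted p = 0.517 with an estimated correlation, 0 called over all genes and 0 adjusted over the list alone). Among genes of other lists without a call in females, Cyp8b1, an enzyme of bile acid synthesis, stood at 148 ± 23.7 against 82.0 ± 11.3 (adjusted p = 0.227), Cyp2c38 at 101 ± 5.37 against 67.7 ± 10.1 (adjusted p = 0.364) and Selenbp2 at 13.2 ± 1.22 against 28.3 ± 5.56 (adjusted p = 0.345).

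**Figure D3:**
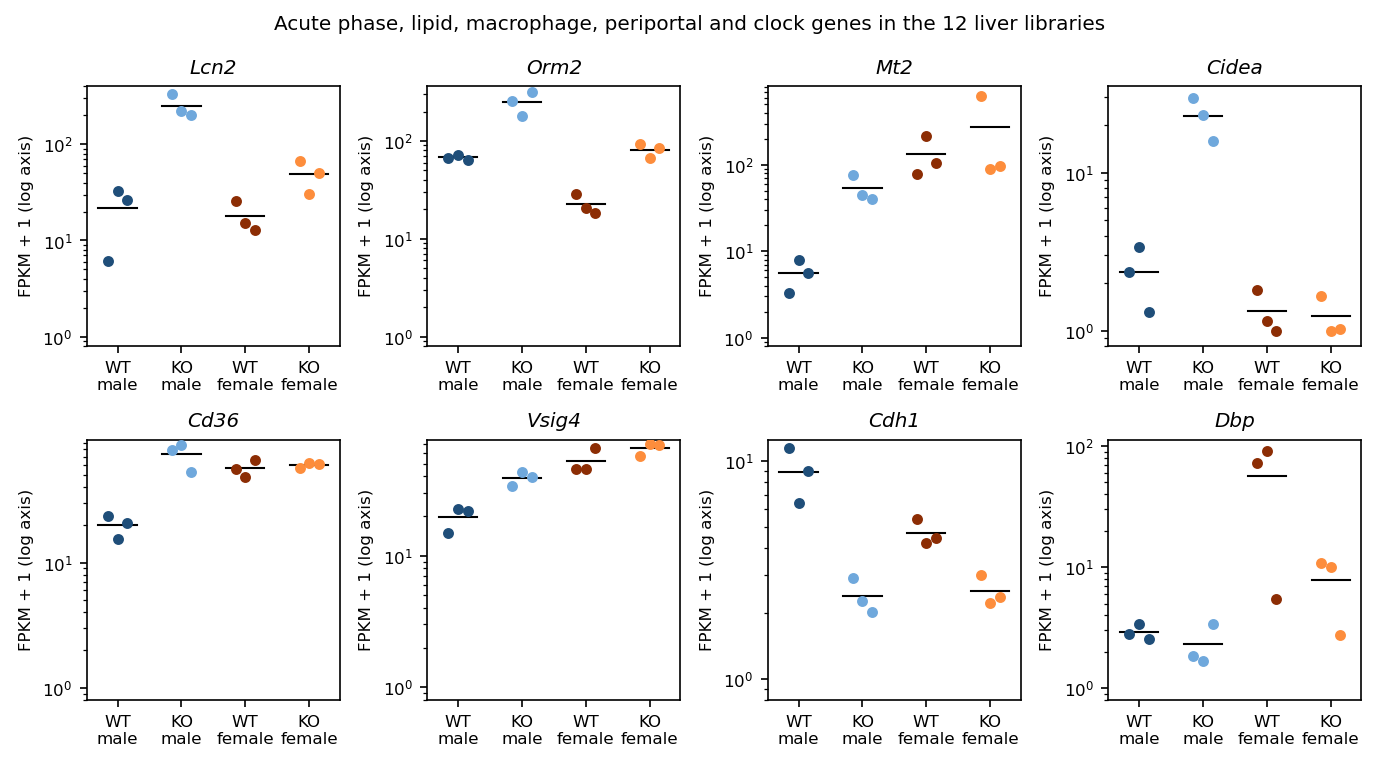
Levels of 8 genes of the acute phase, metal-binding, lipid, macrophage, periportal and clock groups in each library (points) and their group means (lines), as FPKM + 1 on a log axis, for wild-type (WT) and OXR1A-deficient (KO) males and females. Orm2 lies higher in knockouts of both sexes (250 against 66.8 FPKM in males and 80.8 against 21.5 in females), while Dbp ranges from 4.44 to 90.8 within the wild-type females.

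The genotype effect itself differed between the sexes for 3 genes. Cyp2b9 rose in knockout males but stood at 377 ± 74.6 against 431 ± 25.6 FPKM in females (difference of the log2 changes 5.80, SE 0.50, adjusted p = 0.00122). Slc22a27 had a difference of 2.43 (SE 0.33, adjusted p = 0.0436), and Selenbp2, at 13.2 ± 1.22 against 28.3 ± 5.56 FPKM in females, one of -2.15 (SE 0.29, adjusted p = 0.0436). At an unadjusted p under 0.05 limma gave 1040 genes, with a median of 0.20 over all genes that fell to 0.04 with median-ratio scaling. The count was 22 without knockout male 3, 5 without knockout male 2, 2 without wild-type male 3 and 1 without any other library; Cyp2b9 was called whichever library was left out.

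By list, 14 of 26 differed in their genotype effect between the sexes in camera, and none with an estimated correlation, where the lowest adjusted p was 0.0539 for the male-biased list. That list had a median difference of -1.28 (camera adjusted p = 6.49e-33, Selenbp2 called, 11 down adjusted over the list alone), and the female-biased list one of 1.34 (adjusted p = 2.06e-09, and adjusted p = 0.209 with an estimated correlation, Cyp2b9 and Slc22a27 called, 11 up adjusted over the list alone). The endothelial list had a median of 0.69 (adjusted p = 1.16e-08, and adjusted p = 0.209 with an estimated correlation, 0 called, 9 up adjusted over the list alone). Macrophage genes stood at 0.94 (adjusted p = 1.63e-05, and adjusted p = 0.486 with an estimated correlation, 0 called, 7 up adjusted over the list alone) and cholesterol synthesis at 0.84 (adjusted p = 2.69e-05, and adjusted p = 0.486 with an estimated correlation, 0 called, 7 up adjusted over the list alone). Interferon genes had a median of 0.98 (adjusted p = 0.00251, and adjusted p = 0.657 with an estimated correlation), with 0 called also when adjusted over the list alone, and lost the call without wild-type male 1 (0.103). By fry, 4 lists were called: the male-biased, female-biased, lipid uptake and storage, and endothelial lists. The acute phase list was not called (median 0.18, camera adjusted p = 0.907), nor was the circadian list (median 0.60, mean 0.50, camera downwards, adjusted p = 0.903).

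Between wild-type males and females the male-biased list was higher in males and the female-biased list lower. Time of collection is not given and clock genes differed between these groups, so the contrast need not be sex alone. Of the male-biased genes 24 of 25 were higher (24 adjusted over the list alone, median 2.97, camera adjusted p = 2.69e-51, 0.0132 with an estimated correlation), and of the female-biased genes 33 of 34 were lower (34 adjusted over the list alone, median -3.99, 2.01e-33, 0.0141 with an estimated correlation). Elovl3, a fatty acid elongase, was at 229 ± 43.8 FPKM in males against 3.25 in females, and Mup20 at 11670 ± 2482 against 59.0 ± 34.9. The cytochromes P450 Cyp4a12a, Cyp7b1, Cyp8b1 and Cyp2a4 differed by log2 6.44, 2.45, 1.58 and -9.10. Mup14 (5966 ± 2665 FPKM against values of 0, 0.05 and 0), Mup12, Mup11, Serpina1e and Hsd3b5 were among the largest differences towards males. Cyp3a41a (0.640 ± 0.174 against 1795 ± 429), Cyp3a41b, A1bg, Sult2a1, Sult2a2 and Cyp2c69 were among the largest towards females, with Cyp2b9 at log2 -7.98 (SE 0.36, adjusted p = 5.11e-07). The transcription factor Cux2 and Prlr were also higher in females, by log2 -3.17 and -2.97, and Slco1a1 in males by 5.55. Metallothioneins were higher in females, Mt1 by 23.1-fold and Mt2 by 29.1-fold, and so were Cd36 (2.95-fold) and Vldlr (10.6-fold), while the haem enzyme Alas2 was higher in males (6.44-fold).

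Called genes between the wild-type sexes numbered 1539, with 266 higher in males and 1273 higher in females, 3781 at an unadjusted p under 0.05 and 40.2% without overlap (10% by chance). The median log2 difference of all genes was -0.21, so log2 differences between the wild-type sexes are lower by 0.21 than those relative to the median gene. With median-ratio scaling the median was -0.04, with 479 and 577 called; quantile normalization called 586 and 499, and removal of the length trend, chosen after seeing the data, 894 and 658. The count was 708, 675 and 968 without wild-type female 1, 2 and 3, and 1048 to 2081 without any other library.

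Cell type markers differed between the wild-type sexes. This comparison shares the 3 wild-type males with that of knockout and wild type in males, so the 2 are not separate findings. The mean macrophage score was 2.987 to 3.666 in wild-type males and 3.994 to 5.125 in knockout males. It was 4.145 to 4.733 in wild-type females and 4.269 to 4.75 in knockout females, so both differences lay with the lower wild-type males. Sinusoidal endothelial genes were higher in females (13 of 15, with Oit3 2.17-fold, 15 adjusted over the list alone, camera adjusted p = 1.38e-08, and adjusted p = 0.117 with an estimated correlation), as were macrophage genes (9 of 15, with Vsig4 2.77-fold, 11 adjusted over the list alone, 0.000324, and adjusted p = 0.703 with an estimated correlation). Of the clock genes, Nr1d1 stood at 1.65 ± 0.510 in males against 72.2 ± 35.5 FPKM in females and Cry1 at 13.7 ± 2.98 against 2.47 ± 1.70, both called. In all, 2 clock genes were higher and 3 lower in males (2 and 4 adjusted over the list alone) with no list call (median -0.53, camera upwards against other genes, adjusted p = 0.548). Wild-type male 2 was the library poorest in long transcripts.

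Other lists were called between the wild-type sexes with few members called. Of 18 genes of the unfolded protein response, Creld2, known as induced by stress of the endoplasmic reticulum, was higher and the kinase-like Trib3 lower in males (3 up and 1 down adjusted over the list alone, median 0.15). Camera called this list upwards (adjusted p = 0.000434, and adjusted p = 0.471 with an estimated correlation). Interferon genes were lower in all 24 members, 2 of them called, Ifit1 and Oas1a, and 0 when adjusted over the list alone (median -0.95). This difference and the rise in knockout males (median 1.04) share the wild-type males. The median was 0.05 by genotype in females and 0.01 by sex in knockouts. Their camera call (adjusted p = 0.0185, and adjusted p = 0.883 with an estimated correlation) was lost without wild-type male 1 (0.168) or wild-type female 1 (0.0525). Acute phase genes were mixed, with 5 higher in males, among them Orm2, and 4 lower, among them Orm3, Mt1 and Mt2 (6 up and 5 down adjusted over the list alone). The median was 0.11, the mean -0.06 and the camera call upwards (adjusted p = 0.00985, and adjusted p = 0.471 with an estimated correlation). That call was lost without wild-type male 2 (0.062) and with median-ratio scaling (0.111), quantile normalization (0.925) or array weights (0.134). It was also lost among genes with a mean FPKM of at least 5 (0.0763). Lipid uptake and storage (4 genes up and 4 down), bile acid genes (4 up and 1 down) and oxidative stress genes (0 up and 2 down, Hmox1 and Sod3) had medians of -0.03, -0.12 and -0.06. Adjusted over the list alone these counts were 4 and 5, 4 and 3, and 0 and 2. Camera called all 3 upwards against the lower median of all genes (adjusted p = 0.0361, 0.0361 and 0.0496, and adjusted p = 0.321, 0.651 and 0.753 with an estimated correlation), and median-ratio scaling ended the calls (0.158, 0.0642 and 0.0642). The lipid call was also lost without wild-type male 2 (0.218), knockout male 2 (0.0615) or wild-type female 1 (0.0556), and the bile acid call without wild-type male 1 (0.0821), wild-type male 3 (0.075) or wild-type female 1 (0.0525). The oxidative stress call was lost without wild-type male 2 (0.233), knockout male 2 (0.279), knockout male 3 (0.0508), wild-type female 1 (0.0525) or wild-type female 2 (0.0923).

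In knockouts the sexes differed at genes of both sex-biased lists among others, with 423 called, 192 higher in males and 231 higher in females. At an unadjusted p under 0.05 there were 1782, and the median over all genes was -0.01. Time of collection is not given for these groups either, and the clock gene Nr1d1 differed between them. The contrast need not be sex alone. Elovl3 was at 141 ± 60.7 FPKM in males against 5.18 ± 4.13 in females, Cyp4a12a at 133 ± 42.6 against 2.55 ± 3.93, Cyp2d9 at 310 ± 48.4 against 11.3 ± 9.74 and Mup20 at 2617 ± 1437 against 116 ± 64.4. Cyp2b13, Sult2a1, Sult2a2, Sult2a3, A1bg, Cyp2c69 and Cyp3a41a were higher in females, by log2 -5.56 for Cyp2b13 to -7.88 for Cyp3a41a. Of the male-biased list 13 of 25 were higher in males (19 adjusted over the list alone, median 1.71, camera adjusted p = 3.72e-24, 0.0498 with an estimated correlation), and of the female-biased list 29 of 34 were lower (32 adjusted over the list alone, median -2.37, 1.26e-41, 0.0135 with an estimated correlation). Whether these counts differ from those in wild type is covered by the test of the genotype effect between the sexes.

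Some genes of lipid storage and sterol synthesis were higher in knockout males than in knockout females. Cidea, at 22.0 ± 6.98 in males against 0.233 ± 0.379 FPKM in females, Cidec (18.7-fold) and Mogat1 (5.37-fold) were higher in males. The lipid uptake and storage list was called (5 higher and 1 lower, Vldlr, 10 and 2 adjusted over the list alone, median 0.29, 0.000101, 0.0498 with an estimated correlation). Nsdhl, Idi1 and Cyp51 of cholesterol synthesis were higher in males by 2.21-fold, 2.65-fold and 2.20-fold. That list was called too (3 of 24 higher, 8 up and 1 down adjusted over the list alone, 4.36e-06, and adjusted p = 0.445 with an estimated correlation). So was the unfolded protein response, with Dnajb9 and Creld2 among 6 of 18 genes higher (11 adjusted over the list alone, 8.64e-09, and adjusted p = 0.128 with an estimated correlation). Of 18 growth hormone and IGF genes 3 were lower in males (1 up and 5 down adjusted over the list alone, median -0.37, adjusted p = 0.000519, and adjusted p = 0.128 with an estimated correlation). Prlr stood at 50.9 ± 12.5 against 157 ± 39.6, Cux2 at 0.0833 ± 0.0924 against 5.08 ± 2.88 and Igfals at 33.9 ± 13.5 against 67.9 ± 9.89. Acute phase genes were called upwards with 6 of 21 higher in males, among them Orm2, Saa1, Saa2 and Hp (8 up and 2 down adjusted over the list alone, median 0.24, adjusted p = 0.0148, and adjusted p = 0.445 with an estimated correlation). That call was lost without knockout male 1 (0.209), knockout male 3 (0.0616) or knockout female 3 (0.0599).

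Other lists were called by sex in knockouts on few members. Fatty acid oxidation was called upwards with 1 of 29 genes higher in males, the peroxisomal Pex11a (1 up and 1 down adjusted over the list alone, median 0.08, adjusted p = 0.044, and adjusted p = 0.712 with an estimated correlation). It was lost without wild-type male 2 (0.066), knockout male 1 (0.205), knockout male 3 (0.472) or knockout female 3 (0.781). Oxidative stress was called upwards with 1 of 31 higher, the dehydrogenase Ugdh (2 up and 1 down adjusted over the list alone, median 0.14, adjusted p = 0.0148, and adjusted p = 0.544 with an estimated correlation). It was lost without knockout male 2 (0.635) or knockout female 1 (0.109). The periportal list was called downwards with 2 of 11 lower, Gls2 and Hal (1 up and 3 down adjusted over the list alone, median -0.33, adjusted p = 0.0169, and adjusted p = 0.386 with an estimated correlation), and lost the call without knockout female 2 (0.0625). Endothelium was called downwards with 1 of 15 lower, the growth factor Bmp2 (1 down adjusted over the list alone, median -0.18, adjusted p = 0.03, and adjusted p = 0.544 with an estimated correlation), and lost the call without knockout male 3 (0.19) or knockout female 1 (0.109). Macrophage genes were not called (median -0.08, camera adjusted p = 0.772).

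Single libraries also weighed on the sex difference in knockouts. Nr1d1 stood at 8.68 ± 8.35 in males, with 18.2 in knockout male 3, against 45.4 ± 13.6 in females. The count of called genes was 201, 266 and 250 without knockout female 1, 2 and 3, 240 without knockout male 1 and 637 without wild-type male 2. It was 123 without the 3 libraries with traces of the other sex, an alternative chosen after seeing the data.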

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

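The tests of mixing, of transcript length, of the share of hepatocytes and of the removal of 1 library were chosen after the results were seen; the test without the most abundant genes and the regroupings of libraries were chosen before.

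What drew attention here is a difference between the sexes in the effect of the genotype, tested as an interaction. Cyp2b9 had a difference of log2 changes of 5.80, Slc22a27 of 2.43 and Selenbp2 of -2.15. By list, camera gave adjusted p = 6.49e-33 for the male-biased list, 2.06e-09 for the female-biased list, 1.16e-08 for endothelium, 1.63e-05 for macrophages and 2.69e-05 for cholesterol synthesis. It gave 0.00246 for fatty acid oxidation, 0.0498 for lipid uptake and storage, 0.000334 for bile acids, 0.0469 for nuclear and hormone receptors, 0.00251 for interferon and 0.0469 for the unfolded protein response. It gave 0.00246 for periportal, 0.00345 for pericentral and 0.00486 for lymphocyte genes. The male-biased, bile acid, periportal, pericentral and lymphocyte lists lay below other genes in this difference and the rest above. No list was called with an estimated correlation.

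Single libraries ended 6 of these list calls. Fatty acid oxidation lost it without knockout male 3 (0.169) or knockout female 3 (0.112), interferon without wild-type male 1 (0.103), and lymphocyte genes without wild-type male 2 (0.109), knockout male 3 (0.205) or knockout female 3 (0.115). Lipid uptake and storage lost it without wild-type male 1 (0.283) or 3 (0.219), knockout male 1 (0.0567) or 3 (0.179), wild-type female 2 (0.0549) or 3 (0.0618), or knockout female 3 (0.197). Nuclear and hormone receptors lost it without wild-type male 2 (0.161), knockout male 1 (0.197) or 3 (0.0545), wild-type female 2 (0.109), or knockout female 2 (0.0873) or 3 (0.0721). The unfolded protein response lost it without wild-type male 3 (0.176), knockout male 1 (0.108) or 2 (0.0911), wild-type female 1 (0.0758) or 2 (0.103), or knockout female 1 (0.396). Quantile normalization ended the bile acid (0.129), periportal (0.448), pericentral (0.184) and lymphocyte (0.098) calls, and leaving out the 3 libraries with traces of the other sex ended cholesterol synthesis (0.0641), pericentral (0.0641), lipid uptake (0.0705), lymphocyte (0.189) and unfolded protein (0.259) calls. Leaving out the 3 libraries poor in long transcripts ended the receptor (0.314) and lymphocyte (0.123) calls. Array weights ended the pericentral (0.0616), receptor (0.0729) and unfolded protein (0.312) calls, and a pseudocount of 0.1 the lipid uptake (0.109), receptor (0.0549) and unfolded protein (0.0549) calls. A mean FPKM of at least 5 ended lipid uptake (0.0946) and receptors (0.135), no filter on low values unfolded protein (0.0782) and lymphocytes (0.218), and a replicate block unfolded protein (0.0625). The lymphocyte call also ended with median-ratio scaling (0.143) and with the trend with transcript length removed (0.318, and 0.374 with the block).

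When the genotype labels were exchanged in 100 of 200 possible ways, as many called genes as the real 3 came in 6 groupings, the real one included, and as many called lists as the real 14 in 16. These groupings are not free of a genotype effect, since the one with the most called genes (168) exchanged all female labels, so they give no clean chance level and leave the question open.

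The first pattern is the lower male-biased and higher female-biased genes in knockout males. Female liver RNA in knockout males 1 and 2 does not account for it: Xist reached at most 0.22% of the female level, while Cyp2b9 reached 24.8% and 30.4% and other female-biased genes a median of 0.82% and 0.36%. In knockout male 3 the tests do not decide: Xist stood at 2.25% of the wild-type female mean, outside the quartiles of 30 female-biased genes (4.20% to 14.4%), while in a second test, added after that first one was not met, Xist relative to knockout female 3 (2.73%) lay within the quartiles of 9 genes (2.58% to 4.18%), as for 1 of 6 female libraries taken as the source. A trend with transcript length is not the whole cause, since the mean score of the male-biased list differed by -1.694 (SE 0.487) with the trend removed and by -1.515 (SE 0.431) before, and that of the female-biased list by 1.024 (SE 0.442) and 1.215 (SE 0.411). The group difference itself, genotype, remains open as a biological source, and nothing here tells it from unlabelled differences between the animals or from reads shared between related genes.

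The next pattern is the rise of macrophage and sinusoidal endothelial markers in knockout males. In both lists the wild-type males had lower mean scores than every other library, females included. A smaller share of hepatocytes would raise all other cell types alike, but the 2 lists rose above the mean of the lymphocyte, cholangiocyte and stellate lists by 0.646 (SE 0.13). These moved apart as well. The mean score differed by 0.533 (SE 0.253) for stellate cells, near 0.614 (SE 0.127) for endothelium, and by 0.486 (SE 0.228) for neutrophils. The difference was 0.039 (SE 0.537) for lymphocytes and 0.038 (SE 0.163) for cholangiocytes. The log2(FPKM + 1) scale understates rises of low genes. In wild-type males the lymphocyte and cholangiocyte scores were 0.966 to 1.699 and 1.683 to 2.124, against 2.987 to 3.666 for macrophages. The gap alone therefore cannot show a departure from an equal rise, and a smaller share of hepatocytes stays open. Removing the trend with transcript length took the score of the 2 lists from 0.85 (SE 0.206) to 0.648 (SE 0.172). Endothelium alone went to 0.392 (SE 0.04), macrophages from 1.085 (SE 0.395) to 0.905 (SE 0.329) and stellate cells to 0.316 (SE 0.213). The removal also centres each library, taking the median over all genes in males from 0.193 to -0.011. The drops are near that shift, so they show no separate effect of length. The trend is thus not the whole cause for the 2 lists, and for stellate cells its part cannot be told. Whether there were more of these cells or more RNA of these genes per cell was not tested.

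The last pattern is the excess of rises over falls among the genes called in knockout males. The median over all genes was 0.193 by genotype in males and -0.211 by sex in wild type, comparisons that share the wild-type males. It was 0.003 by genotype in females and -0.005 by sex in knockouts. A few abundant genes taking less of the FPKM are not the whole cause: the top 20 genes held 30.8% in wild-type and 26.6% in knockout males, and leaving them out took the median difference from 0.276 to 0.208 in libraries scaled to equal sums, with 214 genes up and 47 down without them. Wild-type male 2, poor in long transcripts, is not the whole cause either, since the median was 0.123 without it. Settings that centre each library fix the median near 0 in advance and decide nothing here. No biological explanation was tested for it.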

How the results depend on the processing

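The alternatives with the length trend removed, without 3 libraries poor in long transcripts and without 3 libraries with traces of the other sex were chosen after seeing the data; the others were planned. No called result of the named genes checked turned its sign, and no list was called in the opposite direction. Without a call, fry pointed the other way for growth hormone, lipogenesis and lymphocyte genes in males. It did so too for lipid uptake and oxidative stress by sex in wild type. Quantile normalization, also without a call, pointed the other way for acute phase genes by sex in wild type (0.925). The fit without the 3 libraries poor in long transcripts did so for lymphocyte genes in males (0.443). Some called members named in the comparisons by sex, such as Creld2, Trib3, Hmox1, Saa1 and Pex11a, were not among the genes checked. Of the 117 called results of named genes checked, 53 were called under every alternative, and of 61 called lists 6. For genotype these were Cyp2b9 and Selenbp2 in males, of 50 named there, no gene in females and Cyp2b9 in the interaction. The other genes were differences between the sexes. Of the lists only the male-biased one in males was a genotype result. All 294 genes called in males kept their direction wherever they were tested. Leaving out a female library, fitting only 2 groups or dropping the variance trend cannot change it, and choosing by p favours it elsewhere. Relative depth of 0.93 to 1.41 limits low genes, for which no counting error was made. Array weights in 1 fit stopped before convergence. Unless fewer genes or libraries account for a change, the cause was not tested.

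With a pseudocount of 0.1, 1 gene was called in females and 5 in the interaction. With no filter 10 lists were called in females. With a mean of at least 5 FPKM, 1 gene was called in females, and 904 genes and 5 lists by sex in wild type. Median-ratio scaling gave 152 and quantile normalization 140 genes in males. Fits of only 2 groups gave 3 genes in males, 6 in females and 216 by sex in knockout. Array weights gave 63, 229, 10 in the interaction and 675 by sex in knockout. With an estimated correlation 1 list was called in males, 0 in females, 0 in the interaction, 2 by sex in wild type and 3 in knockout, and with fry 0 in females, 4 in the interaction and 6 by sex in knockout. Removing the length trend gave 1 gene in females, 10 in the interaction and 745 by sex in knockout. Without the 3 libraries poor in long transcripts 0 were called in females. Without the 3 with traces of the other sex, 125 were called in males (97 of them shared), 0 in females, 525 by sex in wild type and 123 in knockout.

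No steady pairing by replicate number was seen, which does not exclude a shared litter or day. Libraries of the same number correlated at -0.322 to 0.561 (median -0.089, against -0.015 for other pairs), with 6 of 18 pairs above 0.1. As a block the replicate number gave 132 genes in males and 5 in the interaction, and with the length trend removed 194 in males.

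Leaving out each library in turn gave 58 to 570 genes and 15 to 18 lists in males, 0 to 12 and 4 to 9 in females, 1 to 22 and 10 to 15 in the interaction, 675 to 2081 and 7 to 12 by sex in wild type, and 201 to 637 and 10 to 15 by sex in knockout. The log2 change of Oxr1 was 0.164 to 0.61 in males and 0.086 to 0.204 in females.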

Other observations

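The tests on the clock, the acute phase, the summed effect of genotype and the Y-linked traces were chosen after the results were seen; the regroupings of libraries were chosen before.

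The sum of the genotype effects of the sexes was added after the regroupings of the interaction were seen, where exchanging the female labels gave 168 called genes. Of these 126 were up and 42 down, and 116 were also called in males. A sum can be carried by 1 sex alone, as for Cyp2b9 (log2 changes of 5.59 in males and -0.21 in females) and Hsd3b5 (-4.72 and 0.22), so a call there does not show a shared effect. The sign was the same in both sexes for 162 of the 168, which choosing genes by their sum favours in advance. Other genes were chosen after their values were seen, with log2 changes in males and females: Lcn2 3.81 and 1.44, Sult2a7 1.87 and 2.69, Orm2 1.85 and 1.87, Selenbp2 -3.18 and -1.03, and Enho, which encodes the secreted peptide adropin, -1.79 and -1.14. The balance of rises and falls turned with the scaling: median-ratio scaling gave 29 up and 53 down, quantile normalization 58 and 76, and removal of the length trend 145 and 242. The count was 30 (without wild-type female 1) to 238 (without wild-type male 2) with 1 library left out. Over all genes the log2 changes of the sexes had Spearman's rho 0.174.

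One hypothesis was that the acute phase genes respond in both sexes. Across the 21 genes of the list the log2 changes of males and females, which share no library, had rho 0.579. A shared response would give such a rho, which does not tell its source. The 18 genes positive in both sexes add nothing, being the fewest possible with 19 positive in males and 20 in females.

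A further hypothesis was that the livers were taken at different times of day, since the labels give no time. Within groups, the score of Arntl, Clock, Npas2 and Nfil3 ran against that of Dbp, Tef, Per3 and Nr1d1 across the 12 libraries (r = -0.881, exact permutation p = 0.0293 over 1296 permutations). Without wild-type females 2 and 3, the 2 farthest, r was -0.637. The deviations were still taken from the means of all 3 wild-type females, so that of wild-type female 1 rests on the libraries left out. Within the wild-type males the 2 scores ran together, with deviations of 0.241 and 0.095, -0.349 and -0.188, and 0.108 and 0.093. Different times would give the opposed scores seen across the 12 libraries, but a change of the clock itself was not told apart from them. The score of Dbp, Tef, Per3 and Nr1d1 also differed between groups. It was 1.819 to 2.101 in wild-type males, 1.739 to 2.546 in knockout males, 2.941 to 5.735 in wild-type females and 2.622 to 3.608 in knockout females. Time of collection is therefore not told apart from sex in wild type or in knockouts, or from genotype in females.

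Another hypothesis was male liver RNA in wild-type female 1 and knockout female 1. The 4 Y-linked genes stood at a median of 5.58% and 4.42% of the wild-type male level, outside the quartiles of 22 male-biased genes (-0.32% to 2.57% and -2.39% to 2.06%). In a second form of the test, added after this first one was not met, with single male libraries as the source and only 3 genes silent in the other females, the Y-linked share lay within the quartiles for 1 of 6 sources in each library: 4.83% within -5.75% to 7.96% for knockout male 2 in wild-type female 1, and 3.44% within 1.41% to 3.89% for wild-type male 3 in knockout female 1. The Y-linked shares, against 0 to 0.25% in the other females, show reads of male origin in these libraries. Whether they came with male liver RNA is undecided, since the 2 forms of the test disagree and the second rests on 3 genes.

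Regroupings of the 6 libraries in a comparison number only 10, too few for a share under 0.05. The real grouping gave 294 genes in males (highest other 1), 2 in females (1), 1539 by sex in wild type (0) and 423 in knockout (0), each the only one of the 10 to reach its count, 1 of 10. For lists it gave 18 in males (1 of 10, highest other 17), 6 in females (8 of 10 as many, highest other 10), 11 by sex in wild type (3 of 10, highest other 13) and 12 in knockout (5 of 10, highest other 17). In the interaction 6 of 100 groupings reached the 3 genes (highest other 168) and 16 of 100 the 14 lists (highest other 19), but some of these groupings hold the genotype effects themselves.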
